A study of Gallus gallus with 24 samples.

How the data were processed

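The RNA came from the pectoralis major and soleus muscles of Guangyuan Grey hens on 3 diets, with 4 libraries for each of the 6 groups. Per the labels, 270 hens entered the experiment at 150 days of age, 9 birds were selected per diet, both muscles were taken from the selected birds after 12 h of fasting, and the 4 libraries of a group are biological replicates. Tissue came from the ventral side of the pectoralis major and the widest region of the soleus. Which bird gave which library is not given in the sources used here, so the p-values measure only the spread between these samples. Groups were taken from the sample labels. A further sheet lists 30 library names, 5 per muscle and diet, without values, and all 24 libraries with values are used.

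The authors deposited 1 value per gene and library in FPKM, a fragment count scaled to transcript length and to the number of mapped reads. Per the labels' protocols, reads were trimmed with fastp, mapped with HISAT2 to the chicken genome GRCg6a (Ensembl release of April 2022) and assembled and quantified with StringTie v1.3.3b. The submitters' processing notes also list Cufflinks and DESeq2, without versions or roles. The table holds 20780 genes, of which 12264 carry a symbol, 224 are listed at 0 in every library and 13 are mitochondrially encoded. Symbols were used as the table pairs them with Ensembl identifiers; 15 symbols stand on more than 1 identifier. FPKM are shares of each library's total, so a rise of abundant genes lowers the rest, and reads that copies of a gene family share can be assigned to any of them. No counts were used here, and the depth per library is unknown: of 74414 ratios between low values, 4.0% lay within 0.02 of a whole multiple, so no read numbers could be recovered. The precision of low values is therefore not known beyond the spread between libraries.

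The values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean. Genes with at least 1 FPKM in at least 4 libraries were kept, 10944 in all, of which 8873 carry a symbol. All 24 libraries entered 1 fit with a mean per group and 18 residual degrees of freedom, so every comparison shares the estimate of the spread. The 11 comparisons were SOL against PEM within each diet, SHFD and LHFD against CONT and LHFD against SHFD within each muscle, and the difference of each high-fat effect between muscles. All p-values are two-sided, and adjusted p-values are those of limma after Benjamini-Hochberg correction over the genes tested, with a threshold of 0.05. For FPKM the design's branch for normalized values was used, not its count model.

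Before the data were examined, 31 gene lists were fixed. They were slow-type and fast-type sarcomere and calcium handling, glycogen breakdown and glycolysis, the TCA cycle, nuclear and mitochondrially encoded oxidative phosphorylation, fatty acid oxidation, fatty acid uptake and droplet proteins, fatty acid and triglyceride synthesis, and cholesterol synthesis. Further lists were PPAR and PGC-1 regulators and targets, fibre type transcription factors, insulin and amino acid signalling, proteolysis and autophagy, the unfolded protein and heat shock response, oxidative stress, the circadian clock, immediate early genes, the interferon response, cytosolic ribosomal proteins and extracellular matrix. The remaining 10 were markers of fibroblasts, adipocytes, red blood cells, macrophages, lymphocytes, endothelial cells, smooth muscle and pericytes, satellite cells and regenerating fibres, Schwann cells and nerve, and skin epithelium. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 31 lists, again with a correlation estimated from the data, and with fry, which tests whether the genes move one way on balance. Of the camera calls only that of the immediate early genes in PEM, LHFD against SHFD, held with an estimated correlation.

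The rule for the genes named in the text was also fixed then. In the comparison of muscles under CONT and the 4 comparisons of a high-fat diet with CONT, it takes the 10 largest rises and 10 largest falls among called genes with a symbol and a mean of at least 5 FPKM. In the others it takes 3 of each, or the 3 smallest p where none were called. It adds up to 4 members with the smallest p of each list described in that comparison, 13 fixed diet genes and, between muscles, 11 fixed muscle genes. Other called members of a list are named only as such, and some genes are not reported here.

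Alternatives fixed beforehand were quantile normalization, a pseudocount of 0.1, no expression filter, only the groups compared in the fit, the replicate number as a block, marker list means as covariates for the lists, and leaving out each library in turn. After seeing the data, scaling to an equal sum over nuclear-encoded genes, leaving out CONT_PEM 2 and LHFD_PEM 1 together, and the lists under each scaling were added. Whether replicate numbers pair the muscles was checked by correlating the deviations from the group means. In CONT the same-numbered libraries correlated at 0.163 to 0.295, over 0.1 in 4 of 4, so the numbers were taken to pair these libraries, and the count with the replicate block was 5460 against 5554 without. Overlaps between diets sharing controls were compared with simulated unchanged groups, with independent lists and with split controls.

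The steps were tested on simulated data with planted changes in 10944 genes. In a simulated LHFD against CONT in PEM, 31.3% of planted log2 changes of 0.5 were recovered, 91.0% of those of 1 and 97.0% of those of 2, and 3 of 163 called genes were unchanged. In SOL the shares were 22.4%, 89.6% and 95.5%, and 7 of 158 called genes were unchanged. In both, the planted clock list ranked first and camera called 0 others, which leaves correlated genes untested. Recovery in genes with lower values, and with libraries that stand apart, was not tested either. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.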

Results

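Gene expression was measured by RNA sequencing in the pectoralis major (PEM), the large breast muscle, and the soleus (SOL), a muscle of the lower leg, of Guangyuan Grey hens, a chicken breed. The hens received a control diet (CONT), a high-fat diet for 15 days (SHFD) or a high-fat diet for 60 days (LHFD), and were killed at 210 days of age. Each of the 6 muscle-by-diet groups held 4 libraries, 24 in all. The values are FPKM, and the sequencing depth behind them is unknown. Each library's values summed to between 474668 and 525731 FPKM, and 9285 to 10590 genes reached 1 FPKM. The 13 mitochondrially encoded genes took 10.4% to 17.3% of the sum in the PEM libraries and 20.6% to 27.0% in the SOL libraries. No pair of libraries held the same values, the highest correlation being 0.984. CONT_PEM 2, the library numbered 2 of that group, stood furthest from its own group, with a mean correlation of 0.943 and 10484 genes at 1 FPKM or more against 9285 to 9432 in the other 3. Its macrophage marker genes averaged 4.40 and its lymphocyte marker genes 3.27 on the log2 scale, against 2.16 to 2.61 and 1.16 to 1.58 in those 3 libraries. Means below are in FPKM and are given ± SD over 4 libraries. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and a gene is called at an adjusted p under 0.05.

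The first comparison asks how the muscles differ under the control diet. Several slow contractile genes that SOL held at high levels were nearly absent from PEM. MYH7B (2834 ± 1017 against 0.903 ± 1.22, log2 fold change 10.66) encodes a slow myosin heavy chain. TNNI1 (2438 ± 1212 against 1.69 ± 2.95, log2 fold change 10.22) and TNNT1 (1623 ± 565 against 1.19 ± 1.91, log2 fold change 9.80) encode slow troponins I and T. PLN (1589.7 ± 612 against 0.904 ± 1.01, log2 fold change 9.78), the inhibitor of the calcium pump of slow and cardiac fibres, and ATP2A2 (390.4 ± 99 against 3.15 ± 1.16, log2 fold change 6.58), that pump itself, were higher in SOL too. MB (6732 ± 644 against 39.1 ± 14, log2 fold change 7.46) encodes myoglobin, the oxygen store of red muscle. PEM held the fast adult myosin MYH1E (227 ± 102 against 10941 ± 1822, log2 fold change -5.69) and the lactate dehydrogenase subunit LDHA (1070.0 ± 402 against 9263 ± 1193, log2 fold change -3.18). It also held PFKFB3 (3.51 ± 1.85 against 192 ± 153, log2 fold change -5.11), whose product makes an activator of glycolysis. LDHB (549.8 ± 129 against 11.9 ± 9.58, log2 fold change 5.62), the other lactate dehydrogenase subunit, went the opposite way.

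Of 19 tested genes in the slow-type sarcomere and calcium handling list, 16 were higher in SOL and 2 lower, also when adjusted over the list alone. The median log2 fold change was 8.42 (camera adjusted p = 8.7e-10; adjusted p = 0.187 with an estimated correlation). MYL10, MYL3, MYBPC1, MYOZ2, ANKRD2 and LMOD2 were among the 10 largest rises, at log2 fold changes of 10.08, 9.71, 9.34, 8.98, 8.81 and 8.46. The members lower in SOL were TNNC1 (1009 ± 328 against 3638 ± 271, log2 fold change -1.90), the troponin C of slow and cardiac muscle, and SLN, the small calcium pump regulator sarcolipin, with a log2 fold change of -1.05. The fast-type list was mixed, with 4 of 17 genes higher and 7 lower in SOL (5 and 7 adjusted over the list alone), a median of -0.64 and a camera adjusted p of 0.131, CONT_SOL 3 standing apart with a list mean of 8.83 against 9.54 to 9.62 in the other 3. TPM1 and RYR3, with MYH1E, were among those lower, at -2.28 and -1.06, and so was TNNI2 at -1.02, whose adjusted p of 0.0141 was 0.0669 without the expression filter. PVALB (10.8 ± 8.34 against 0.236 ± 0.224, log2 fold change 2.99), the calcium buffer parvalbumin, ACTN2 at 0.84, and the myosins MYH1C and MYH1D at 2.14 and 1.66 went against the list's name. Besides MYH1E and PFKFB3, the 10 largest falls were MYBPHL, FRMD5, PRKAG3, SIM2, NTMT2, BPGM, JPH3 and NRGN, at log2 fold changes from -5.93 for MYBPHL to -4.25 for NRGN. PRKAG3 (5.63 ± 3 against 163 ± 7.83) encodes a muscle subunit of AMP-activated kinase, and BPGM (26.9 ± 5.98 against 555 ± 21.1) the enzyme that makes 2,3-bisphosphoglycerate.

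Genes of energy metabolism separated the muscles by pathway. In the list of glycogen breakdown and glycolysis 13 of 19 genes were lower in SOL and 2 higher, LDHB and the hexokinase HK2, with a median of -2.16 (camera adjusted p = 7.4e-07; adjusted p = 0.190 with an estimated correlation). GPI, PGAM1 and GPD1 had log2 fold changes of -2.93, -2.82 and -3.59. Of 22 TCA cycle genes, 16 were higher in SOL and 1, the pyruvate carboxylase PC, lower (camera adjusted p = 7.4e-07; adjusted p = 0.200 with an estimated correlation). CS (304 ± 30 against 108 ± 18.1, log2 fold change 1.5), the citrate synthase, IDH2 at 2.32 and MDH1 at 2.0 led them. Of 58 nuclear genes of oxidative phosphorylation, 48 were higher in SOL and 0 lower, with a median of 0.76 (camera adjusted p = 4.7e-14; adjusted p = 0.190 with an estimated correlation), COX6A1 reaching 4.17. All 13 mitochondrially encoded genes were higher, for example MT-CO1 (24493 ± 1421 against 11006 ± 2019, log2 fold change 1.17), a cytochrome oxidase subunit (camera adjusted p = 1.2e-05; adjusted p = 0.294 with an estimated correlation). Of 26 genes of fatty acid oxidation, 21 were higher and 1 lower, with a median of 1.51 (camera adjusted p = 8.7e-10; adjusted p = 0.187 with an estimated correlation). ETFA, ECI1, CPT2 and ACAT1 stood at 2.35, 2.0, 1.85 and 1.73, while CPT1A, which loads long-chain fatty acids for entry into mitochondria, was the member lower in SOL at -1.40. Adjusted over the list alone, these counts were 2 higher and 13 lower, 16 and 1, 52 and 0, 13 and 0, and 21 and 1.

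In the list of fatty acid uptake, binding and droplet proteins, 9 of 21 genes were higher in SOL and 3 lower, the same numbers adjusted over the list alone (camera adjusted p = 0.112). CD36 (159 ± 62.3 against 2.38 ± 0.887, log2 fold change 5.52), a fatty acid transporter, FABP3 (3043 ± 1351 against 117 ± 27.3, log2 fold change 4.60), the fatty acid binding protein of heart and muscle, and FABP5 at 2.24 were higher. DGAT2 (4.07 ± 0.832 against 34.8 ± 7.64, log2 fold change -2.81), which makes triglyceride, VLDLR and LPIN1 were lower. Of 21 genes of fatty acid and triglyceride synthesis 13 were higher and 6 lower (13 and 6 adjusted over the list alone; camera adjusted p = 0.220). Of 20 genes of cholesterol synthesis 9 were higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 0.211), or 3 and 2 after quantile normalization. Among 19 PPAR and PGC-1 regulators and targets, 7 were higher and 6 lower, the same adjusted over the list alone, and camera's direction was down although median and mean were 0.20 and 0.13 (adjusted p = 0.767). PPARGC1A at 1.74 and ESRRB at 1.93 were higher and RXRA at -2.02 and NRF1 at -1.19 lower. Of 19 fibre type transcription factors 8 were higher and 2 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.438). PROX1 at 1.60, TBX1 at 1.61 and RCAN1 at 2.10, a target of calcineurin, were higher, and SOX6 at -1.40, a repressor of slow genes, lower.

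Markers of several other cell types were higher in SOL alongside these groups. The numbers higher and lower were 14 and 0 of 16 endothelial genes (camera adjusted p = 1.1e-04; adjusted p = 0.190 with an estimated correlation) and 12 and 0 of 14 smooth muscle and pericyte genes (3.4e-04; adjusted p = 0.187 with an estimated correlation). They were 9 and 1 of 13 adipocyte genes (0.00223; adjusted p = 0.187 with an estimated correlation) and 10 and 1 of 15 satellite cell and regenerating fibre genes (0.00734; adjusted p = 0.187 with an estimated correlation). KDR, a receptor on vessels, CNN1, a smooth muscle protein, PLIN1, a coat protein of fat droplets, and CHRNA1, an acetylcholine receptor subunit, had log2 fold changes of 1.54, 5.47, 3.23 and 2.56, and DGAT2 and PAX7 were the members lower. Of 29 extracellular matrix genes 21 were higher and 0 lower (camera adjusted p = 3.5e-04; adjusted p = 0.552 with an estimated correlation), among them COL4A1 at 1.51, and the camera adjusted p was 0.228 with the fibroblast marker level as a covariate. Fibroblast genes numbered 7 higher and 0 lower of 15 (camera adjusted p = 0.0573), Schwann cell and nerve genes 4 and 0 of 7 (0.0754), red blood cell genes 2 and 1 of 10 (0.406) and skin epithelium genes 1 and 2 of 3 (0.703). Macrophage genes numbered 1 and 2 of 12 (0.937) and lymphocyte genes 0 and 1 of 11 (0.588); camera's direction for both was down, while the medians were 0.36 and 0.12 and the means 0.23 and -0.08. Adjusted over the list alone the counts were 14 and 0, 12 and 0, 9 and 1, 11 and 1, 22 and 0, 7 and 0, 4 and 0, 2 and 1, 1 and 2, 0 and 1, and 0 and 1.

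Of 30 genes of the unfolded protein and heat shock response, 15 were higher in SOL and 2 lower (camera adjusted p = 0.0304; adjusted p = 0.552 with an estimated correlation). Of 21 interferon response genes 10 were higher and 0 lower (camera adjusted p = 0.0324; adjusted p = 0.680 with an estimated correlation). With the adipocyte marker level as a covariate the camera adjusted p were 0.614 and 0.978, the interferon list turning to down, while the immediate early list was called up (8.0e-06; 0.0403 with the fibroblast level) and the ribosomal list down (0.0154). They were 0.0940 for the first list with the red blood cell level and 0.0682 for the other with the fibroblast level. Oxidative stress genes numbered 13 higher and 3 lower of 26 (camera adjusted p = 0.0794), immediate early genes, which respond within minutes to stimuli, 9 and 0 of 20 (0.0534), and insulin and amino acid signalling genes 5 and 10 of 25 (0.0552). Muscle proteolysis and autophagy genes numbered 8 higher and 9 lower of 29 (camera adjusted p = 0.192) and circadian clock genes 4 and 6 of 15 (0.343). Cytosolic ribosomal protein genes numbered 16 and 2 of 62 (camera adjusted p = 0.343), a majority that turned to 3 and 7 after quantile normalization. Adjusted over the list alone these were 16 and 2, 10 and 0, 13 and 3, 9 and 0, 5 and 10, 8 and 9, 4 and 6, and 12 and 2. Across all 10944 genes tested, 3365 were higher and 2189 lower in SOL, so that 60.6% of the calls were higher, against 43.0% after quantile normalization and 72.1% after scaling to an equal nuclear-encoded sum. The median log2 fold change of all genes was 0.12 here, -0.07 after quantile normalization and 0.23 after nuclear scaling, so small changes are relative to the scaling.

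**Figure D1:**
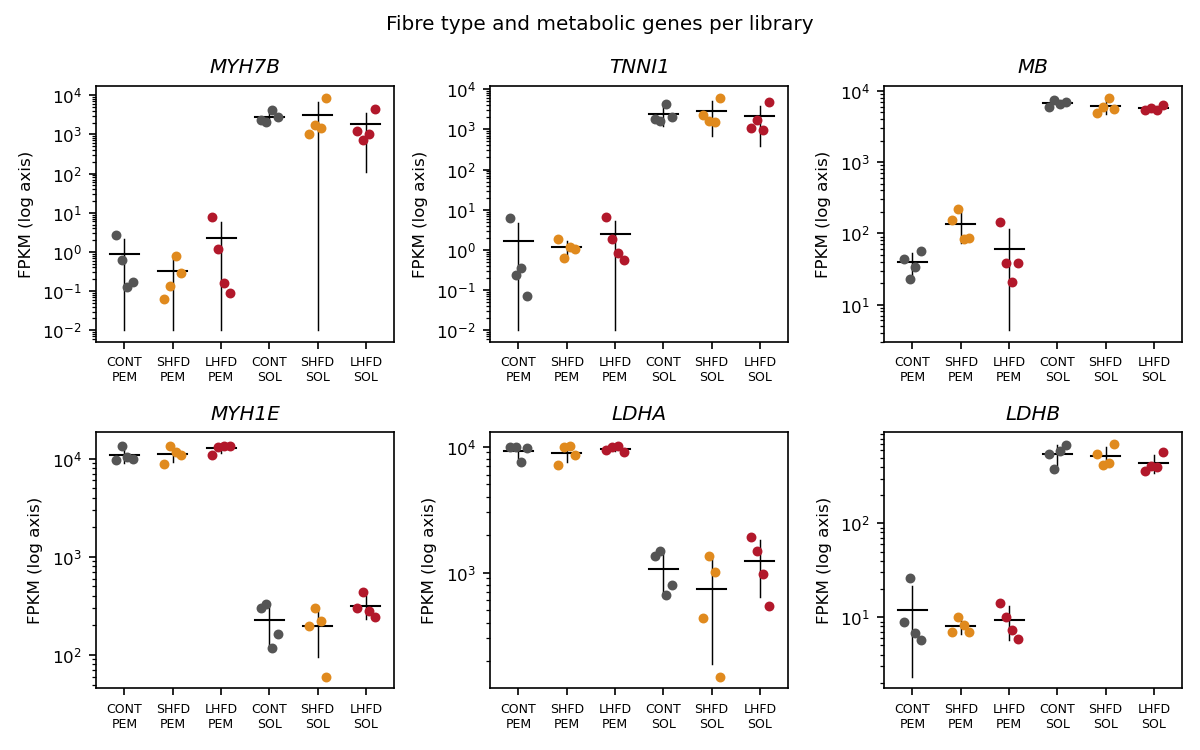
FPKM per library, on log axes with a different range in each panel, of MYH7B, TNNI1, MB, MYH1E, LDHA and LDHB in the 6 muscle-by-diet groups (points, libraries; horizontal lines, means; vertical lines, ± SD, drawn down to 0.01 where it would fall below). MB averaged 6732 ± 644 in CONT_SOL and 39.1 ± 14 in CONT_PEM, while LDHA averaged 1070.0 ± 402 and 9263 ± 1193.

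Many of the same genes separated the muscles under both high-fat diets. In SHFD the slow myosin MYH7B (3222 ± 3662 against 0.318 ± 0.328, log2 fold change 10.72) and MYL10 (2639 ± 2367 against 0.614 ± 0.674, log2 fold change 10.39), a myosin light chain, were higher in SOL. MYH1E (195 ± 99.5 against 11262 ± 1959.6, log2 fold change -6.04), BPGM (13.5 ± 6.2 against 488 ± 91.7, log2 fold change -5.15) and FRMD5 at -5.13 were lower. In LHFD MYH7B (1857 ± 1745 against 2.27 ± 3.64, log2 fold change 9.33) and TNNI1 (2145 ± 1764 against 2.43 ± 2.77, log2 fold change 9.28) were higher. There MYH1E (317 ± 86.2 against 12784 ± 1294, log2 fold change -5.36), MYBPHL (14.5 ± 6.82 against 664 ± 117, log2 fold change -5.53) and SIM2 at -4.93 were lower. LDHA stood at -4.02 in SHFD and -3.11 in LHFD, LDHB at 5.85 and 5.45, CS at 1.3 and 1.54, FABP3 at 3.90 and 3.92, and MB at 5.58 and 6.93. MYBPC1 was higher at 6.67 and 7.53, PVALB at 2.76 and 3.63, and TNNC1 lower at -1.54 and -2.18. TNNI2 was lower in SHFD (log2 fold change -1.3, adjusted p = 0.00259) and was at -0.75, still called, without SHFD_SOL 4, which held 1320.0 FPKM against 5494 to 6360.0 in the other 3. In LHFD its log2 fold change of -0.68 had an adjusted p of 0.0998, or 0.0155 with only the 8 libraries compared in the fit.

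Nuclear genes of oxidative phosphorylation numbered 49 higher in SOL and 0 lower of 58 in SHFD (camera adjusted p = 2.0e-15; adjusted p = 0.157 with an estimated correlation) and 56 and 0 in LHFD (1.4e-19; adjusted p = 0.147 with an estimated correlation). Fatty acid oxidation genes numbered 20 and 1 in SHFD (6.5e-09; adjusted p = 0.133 with an estimated correlation) and 22 and 0 in LHFD (6.2e-11; adjusted p = 0.147 with an estimated correlation). Glycolysis genes numbered 3 higher and 13 lower in SHFD, LDHB, ENO1 and ALDOC being those higher (3.6e-06; adjusted p = 0.206 with an estimated correlation), and 1 and 13 in LHFD (1.4e-08; adjusted p = 0.147 with an estimated correlation). Adjusted over the list alone these counts were the same except for 50 and 0 of oxidative phosphorylation in SHFD. Ribosomal protein genes numbered 37 higher and 1 lower in SHFD (camera adjusted p = 6.5e-06; adjusted p = 0.612 with an estimated correlation, and 0.137 with the adipocyte marker level as a covariate; 41 and 1 adjusted over the list alone), or 16 and 2 after quantile normalization. In SHFD 2901 genes were higher and 2745 lower, 51.4% of the calls being higher, against 57.7% with nuclear scaling and 43.5% after quantile normalization. In LHFD 3163 were higher and 1632 lower, 66.0%, against 74.9% and 43.3%.

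The next comparison asks what 15 days of high-fat diet changed in PEM. Among the genes that rose were MYOT (134 ± 20.6 against 45.2 ± 7.65 FPKM, log2 fold change 1.55, adjusted p = 0.00676), a Z-disc protein, and SMPX (14.1 ± 11.6 against 2.36 ± 0.619 FPKM, log2 fold change 1.91, adjusted p = 0.0141), a small muscle protein. SYNPO2L (140.0 ± 23.4 against 58.6 ± 7.12 FPKM, log2 fold change 1.23, adjusted p = 0.0101), an actin-binding protein of the sarcomere, and AOX2 (16 ± 7.17 against 4.55 ± 0.492 FPKM, log2 fold change 1.51, adjusted p = 0.0133), an aldehyde oxidase, rose too. KLHL40, a stabiliser of thin filament proteins, FKBP5, a chaperone induced by glucocorticoids, and MB had rises of 2.32, 2.28 and 1.72, with adjusted p of 0.0415, 0.0479 and 0.0319. Genes that fell included NEDD4 (2.94 ± 0.217 against 9.75 ± 4.79 FPKM, log2 fold change -1.36, adjusted p = 0.00681), a ubiquitin ligase, and ITGB5 (8.65 ± 2.2 against 22.2 ± 6.69 FPKM, log2 fold change -1.24, adjusted p = 0.0101), an integrin subunit. HMGB2 (2.2 ± 0.246 against 6.91 ± 3.22 FPKM, log2 fold change -1.22, adjusted p = 0.0104), a chromatin protein, fell as well. G0S2, an inhibitor of fat droplet lipase, GLUL, the glutamine synthetase, and LPIN1, a phosphatidate phosphatase, fell by 2.19, 1.87 and 1.32 on the log2 scale, with adjusted p of 0.0359, 0.0181 and 0.0167. NRIP1, GOLGA4 and KIAA2026 also rose, at 1.22, 1.15 and 1.12, and SLC41A3, CTSV, ANKRD9 and FXYD6 also fell, at -1.41, -1.37, -1.26 and -1.09.

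Of the fixed diet genes, PDK4, which turns off pyruvate oxidation, had the largest difference in PEM but did not pass (45 ± 26.4 against 178 ± 136 FPKM, log2 fold change -1.69, adjusted p = 0.268). Nor did CPT1A at -0.12, ANGPTL4 at 0.06, PLIN2 at 0.33, CD36 at 0.46, LPL at 0.62, FABP3 at 0.09, FABP4 at -0.87, ADIPOQ at -0.23, FASN at -0.03, PPARGC1A at 0.23 or UCP3 at 0.36 pass. SCD, at a mean of 0.42 FPKM over all libraries, was below the expression filter. In the lists, 2 of 21 uptake and droplet genes fell, G0S2 and LPIN1 (2 adjusted over the list alone; camera adjusted p = 0.687, direction down, with a median of 0.06 and a mean of -0.16). Of 21 synthesis genes 1, PNPLA3, rose and 1, LPIN1, fell (1 and 3 adjusted over the list alone). Of 29 proteolysis and autophagy genes 1, NEDD4, fell (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0235; adjusted p = 0.932 with an estimated correlation). The ubiquitin ligase TRIM63 and its regulator KLF15 had log2 fold changes of -1.73 and -1.52, with adjusted p of 0.0849 and 0.0664. In the clock list 1 of 15 genes rose, PER2 (8.13 ± 3.2 against 3.27 ± 0.789 FPKM, adjusted p = 0.0167), a repressor of the clock (2 adjusted over the list alone; camera adjusted p = 0.160). TCA cycle genes had a median of 0.22 with 0 of 22 called (2 higher adjusted over the list alone; camera adjusted p = 7.9e-07), and heat shock genes 0.22 with 0 of 30 (2 higher adjusted over the list alone; 6.1e-04). Ribosomal protein genes had a median of -0.16 and interferon genes of -0.35, with 0 called in each, also adjusted over the list alone (camera adjusted p = 2.3e-04 and 0.00497), and immediate early genes likewise 0 of 20 (0.574). Nuclear and mitochondrially encoded genes of oxidative phosphorylation had medians of 0.08 and 0.19, also with 0 called and 0 adjusted over the list alone (camera adjusted p = 0.00497 and 0.00126). With an estimated correlation the adjusted p was 0.932 for each of these lists. Lymphocyte markers had a median of -0.47 (1 lower adjusted over the list alone; camera adjusted p = 0.00531; adjusted p = 0.932 with an estimated correlation), CONT_PEM 2 standing apart at a list mean of 3.27 against 1.16 to 1.58 in the other 3 CONT_PEM libraries. Smooth muscle and pericyte markers had a median of 0.13 (1 higher adjusted over the list alone; 0.0300; adjusted p = 0.932 with an estimated correlation).

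In all, 59 genes rose and 58 fell under SHFD in PEM. The count depended on the fit. With only the 8 libraries compared it was 0 in limma, and all 21 called genes named by rule lost their call, with adjusted p from 0.0517 to 0.284, while 1444 genes had an unadjusted p under 0.05 in the fit of all libraries. It was 63, 116, 47 and 106 without SHFD_PEM 1, 2, 3 and 4 and 68, 173, 65 and 148 without CONT_PEM 1, 2, 3 and 4. The numbers of named genes that lost their call were then 11, 4, 9 and 6, with adjusted p up to 0.131, 0.0981, 0.166 and 0.107, and 7, 4, 8 and 3, with adjusted p up to 0.129, 0.0900, 0.140 and 0.0832. Without the expression filter 7 lost it (up to 0.1002), without CONT_PEM 2 and LHFD_PEM 1 together 2 (0.0987), with nuclear scaling 2 (0.0633) and 1 each after quantile normalization and with a pseudocount of 0.1. SMPX, MYOT, AOX2, SYNPO2L, GOLGA4, KIAA2026, NEDD4, ITGB5 and HMGB2 kept theirs in each of these 8 fits. Without CONT_PEM 2, PDK4 (0.0406), SLC27A1 (0.0189), KLF15 (0.0120) and TRIM63 (0.0187) passed as lower. PDHB passed after quantile normalization (0.0283), NR1D2 without SHFD_PEM 2 (0.0383) and HSPH1 without SHFD_PEM 4 (0.0485).

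After 60 days of high-fat diet, 6 of 20 immediate early genes and 3 of 15 clock genes rose in PEM against the control diet. The immediate early list had a camera adjusted p of 3.9e-11 (adjusted p = 0.185 with an estimated correlation) and the clock list one of 0.134. XIRP1 (276 ± 106 against 19.2 ± 8.56 FPKM, log2 fold change 3.79, adjusted p = 6.7e-04) encodes an actin-binding repair protein of muscle. KLHL40 (546 ± 194 against 52.2 ± 20.7 FPKM, log2 fold change 3.37, adjusted p = 0.00152) and ABRA, an activator of actin signalling, at 3.73 (adjusted p = 0.00232) were among the largest rises. ATF3 (210.3 ± 58.4 against 17.1 ± 6.82 FPKM, log2 fold change 3.61, adjusted p = 0.00534) and NR4A3 (29.5 ± 17.2 against 5.04 ± 7.01 FPKM, log2 fold change 2.77, adjusted p = 0.00376) are transcription factors induced by stress and exercise. TET2 (23.3 ± 13.8 against 1.02 ± 0.311 FPKM, log2 fold change 3.4, adjusted p = 6.0e-04) encodes an enzyme that oxidises methylcytosine. Genes of lipid handling that fell included G0S2 (13.7 ± 16.3 against 76.2 ± 27.9 FPKM, log2 fold change -2.88, adjusted p = 0.00258) and CPT1A (7.27 ± 2.85 against 21.2 ± 3.08 FPKM, log2 fold change -1.47, adjusted p = 0.00152). DGAT2 (12.1 ± 9.32 against 34.8 ± 7.64 FPKM, log2 fold change -1.64, adjusted p = 0.00168) fell too, as did AGPAT2 (0.835 ± 0.436 against 5.36 ± 1.95 FPKM, log2 fold change -1.78, adjusted p = 5.1e-04), an enzyme of phospholipid and triglyceride synthesis. Other rises among the 10 largest were CRISPLD2 at 2.53, ANKRD1 at 3.73, RRAD at 3.4 and FKBP5 at 2.37, and other falls SSH2 at -1.88, ASB2 at -1.93, ALPK1 at -1.93, GADD45G at -1.88, NXNL1 at -1.77, GLUL at -1.79 and CA12 at -2.08.

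Of 20 immediate early genes 6 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 1.03. Besides ATF3 and NR4A3 they were MAFF at 2.22, KLF6 at 1.5, FOSL2 at 1.56 and NR4A1 at 1.33. Of 15 clock genes 3 rose and 0 fell (3 and 2 adjusted over the list alone). They were the clock repressors PER2 (13.5 ± 3.51 against 3.27 ± 0.789 FPKM, log2 fold change 1.75, adjusted p = 1.6e-04), NR1D2 (17.7 ± 3.32 against 6.91 ± 0.848 FPKM, log2 fold change 1.23, adjusted p = 0.00198) and PER3 (1.44 ± 0.322 against 0.547 ± 0.113 FPKM, log2 fold change 0.65, adjusted p = 0.00737). The clock list's median was -0.08 and its mean 0.17, with camera's direction up. Of 21 uptake and droplet genes 0 rose and 5 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.454), G0S2, DGAT2, LPIN1 at -1.52, the fatty acid transporter SLC27A1 at -1.87, and VLDLR at -0.64. Of 21 synthesis genes 1, PNPLA3, rose and 3, AGPAT2, DGAT2 and LPIN1, fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.240). Of 26 fatty acid oxidation genes 0 rose and 2 fell, CPT1A and ACSL1 (16.4 ± 3.05 against 34.2 ± 7.46 FPKM, adjusted p = 0.0186), which activates long-chain fatty acids (2 adjusted over the list alone; camera adjusted p = 0.189). Of 25 insulin and amino acid signalling genes 1 rose, SOCS3, an inhibitor of cytokine signalling, and 5 fell, the same adjusted over the list alone, and camera's direction was up with a median of -0.01 (adjusted p = 0.930). IRS1, a docking protein of the insulin receptor, TBC1D4, a regulator of glucose transporter traffic, INSR and IRS4 fell by 1.14, 1.11, 0.74 and 0.71.

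Of 29 proteolysis and autophagy genes 1, MUSTN1, rose and 3 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.189), NEDD4 at -0.95, the autophagy kinase ULK1 at -1.43 and BNIP3L at -0.40. Of 19 PPAR and PGC-1 genes 1, ESRRB, rose and 3 fell, CPT1A, PPARD and TFAM (1 and 4 adjusted over the list alone; camera adjusted p = 0.669). Of 29 extracellular matrix genes 2 rose, THBS1 at 1.47 and TIMP3 at 1.07, and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 1.9e-05; adjusted p = 0.976 with an estimated correlation). Beside these groups, smooth muscle and pericyte markers had a median of 0.25 with 0 of 14 called, also adjusted over the list alone (camera adjusted p = 0.00325; adjusted p = 0.586 with an estimated correlation). Slow-type genes had a median of 0.24 with 0 of 19 called, also adjusted over the list alone, and of 30 unfolded protein and heat shock genes 1 rose (1 adjusted over the list alone). Both lists had a camera adjusted p of 0.0182 and an adjusted p of 0.976 with an estimated correlation. The lymphocyte marker CD4 had a log2 fold change of -0.83, with CONT_PEM 2 apart in that list. Of the other fixed genes, PLIN2, a droplet coat protein, had 24.4 ± 5.13 against 13.5 ± 2.71 FPKM (log2 fold change 0.81, adjusted p = 0.0738). None of PDK4 at -0.91, ANGPTL4 at -0.33, CD36 at -0.11, LPL at 0.77, FABP3 at -0.44, FABP4 at 0.04, ADIPOQ at -0.24, FASN at 0.16, PPARGC1A at 0.15 and UCP3 at -0.20 passed.

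In all, 224 genes rose and 536 fell under LHFD in PEM, so that 29.5% of the calls were rises, against 48.1% after quantile normalization (318 and 343) and 36.3% with nuclear scaling. With only the 8 libraries compared 69 genes were called, and 27 of the 40 called genes named by rule lost their call, with adjusted p up to 0.238. The count was 666, 393, 579 and 587 without LHFD_PEM 1, 2, 3 and 4 and 446, 953, 402 and 713 without CONT_PEM 1, 2, 3 and 4. The numbers of named genes that lost their call were then 8, 6, 4 and 6, with adjusted p up to 0.122, 0.144, 0.129 and 0.104, and 9, 3, 12 and 3, with adjusted p up to 0.101, 0.0916, 0.142 and 0.0630. Without the expression filter 7 lost it (up to 0.0857), without CONT_PEM 2 and LHFD_PEM 1 together 6 (0.181), after quantile normalization 3 (0.169) and 1 each with nuclear scaling and a pseudocount of 0.1. XIRP1, ATF3, TET2, KLHL40, CRISPLD2, ASB2, SSH2, AGPAT2, CPT1A, MAFF, PER2 and NR1D2 kept theirs in all alternatives run. Without CONT_PEM 2, FASN (0.0438), TIMP2 (0.00706) and TGFB3 (0.0408) passed as higher, as HADH, at -0.43, did as lower without LHFD_PEM 1 (0.0493).

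**Figure D2:**
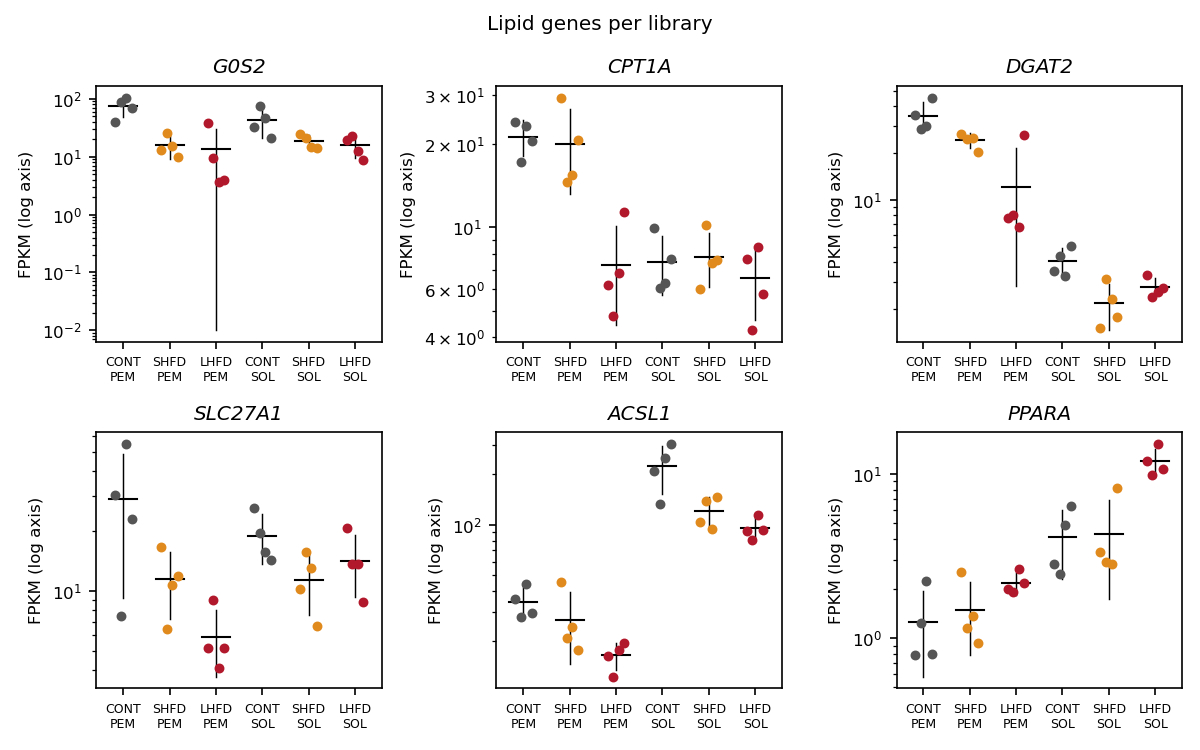
FPKM per library, on log axes with a different range in each panel, of the lipid genes G0S2, CPT1A, DGAT2, SLC27A1, ACSL1 and PPARA in the 6 groups (points, libraries; horizontal lines, means; vertical lines, ± SD, drawn down to 0.01 where it would fall below). CPT1A averaged 7.27 ± 2.85 in LHFD_PEM against 21.2 ± 3.08 in CONT_PEM, and 6.55 ± 1.93 in LHFD_SOL against 7.47 ± 1.78 in CONT_SOL.

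Between the high-fat diets in PEM, 2 of 20 immediate early genes were higher after 60 than after 15 days, and the camera call of the list held with an estimated correlation (camera adjusted p = 5.3e-22; adjusted p = 0.0110 with an estimated correlation). NR4A3 (29.5 ± 17.2 against 2.03 ± 1.47 FPKM, log2 fold change 3.29, adjusted p = 0.00773) and KLF6 (24.6 ± 13.4 against 3.8 ± 0.414 FPKM, log2 fold change 2.25, adjusted p = 0.00438) rose. With adjustment over the list alone 12 were higher and 0 lower, and its median was 1.08. SLC4A4, a bicarbonate transporter, also rose at 1.57, and CPT1A (7.27 ± 2.85 against 20 ± 6.79 FPKM, log2 fold change -1.35, adjusted p = 0.0153), WDR53 at -0.77 and RRS1 at -0.75, a factor of ribosome assembly, fell. Fatty acid oxidation genes had a median of -0.27 with 1 of 26 lower, CPT1A, also adjusted over the list alone (camera adjusted p = 8.3e-04; adjusted p = 0.668 with an estimated correlation). Nuclear oxidative phosphorylation genes (-0.20), TCA cycle genes (-0.22; 2 lower adjusted over the list alone), extracellular matrix genes (0.33), macrophage markers (0.21) and lymphocyte markers (0.18) had camera adjusted p of 4.9e-07, 3.5e-05, 1.9e-05, 0.0434 and 0.0481. Each had adjusted p = 0.668 with an estimated correlation and 0 members called, 0 also adjusted over the list alone except for the TCA cycle. LHFD_PEM 1 stood apart, with a lymphocyte mean of 2.55 against 1.29 to 1.33 in the other 3 of its group, and had the highest macrophage mean, 3.55 against 2.19 to 2.68. With the fibroblast marker level as a covariate the matrix, macrophage and lymphocyte lists had 0.193, 0.827 and 0.827, and with the red blood cell level the last 2 had 0.0771 and 0.129. Slow-type genes (0.21), cholesterol synthesis genes (0.11), ribosomal protein genes (0.09) and fibroblast markers (0.26) also had 0 called and 0 adjusted over the list alone. Their camera adjusted p were 0.0434, 0.0333, 0.000205 and 0.00427, with an adjusted p of 0.668 with an estimated correlation for each. With the fibroblast level as a covariate the first 3 had 0.0939, 0.0939 and 0.502, and slow-type genes 0.129 with the red blood cell and 0.0515 with the adipocyte level. The fixed genes other than CPT1A did not pass, from CD36 at -0.57 to FABP4 at 0.91. In all, 13 genes were higher and 9 lower. The count was 10 with only the 8 libraries compared, 11 after quantile normalization and 12 with nuclear scaling. It was 9, 10, 16 and 23 without LHFD_PEM 1, 2, 3 and 4 and 11, 30, 11 and 10 without SHFD_PEM 1, 2, 3 and 4. NR4A3 and KLF6 kept their call in those 8 fits, but with only the 8 libraries compared KLF6, CPT1A, WDR53 and RRS1 lost it (adjusted p from 0.0763 to 0.308) and BTG2 passed (0.00543). CPT1A also lost it without LHFD_PEM 1 or 2 or SHFD_PEM 1 or 4. RRS1 lost it without the same libraries, and WDR53 and SLC4A4 also without others, with adjusted p up to 0.192. After quantile normalization 3 of the 6 called genes named by rule lost it (up to 0.0938), without the expression filter 2 (0.123), with nuclear scaling 2 (0.0627) and without CONT_PEM 2 and LHFD_PEM 1 together 4 (0.106).

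In SOL, the genes that rose after 15 days of high-fat diet included some for chaperones. HSPA4 (159.9 ± 44.8 against 68 ± 14.9 FPKM, log2 fold change 1.21, adjusted p = 0.0109) and HSPH1 at 1.55, cochaperones of the heat shock 70 proteins, and DNAJB4 (108 ± 31.8 against 49.6 ± 12.7 FPKM, log2 fold change 1.09, adjusted p = 0.034) rose. So did XIRP1 (520.0 ± 416 against 69.9 ± 20 FPKM, log2 fold change 2.62, adjusted p = 0.0375) and AFAP1 (5.7 ± 1.36 against 2.28 ± 0.632 FPKM, log2 fold change 1.03, adjusted p = 0.0102), an actin filament protein. FGF1 (3.62 ± 2.35 against 12.6 ± 2.79 FPKM, log2 fold change -1.66, adjusted p = 0.0186), a fibroblast growth factor, GPAT3 (19.3 ± 2.29 against 43.3 ± 16.2 FPKM, log2 fold change -1.05, adjusted p = 0.0375), an enzyme of triglyceride synthesis, and FAHD1, a mitochondrial enzyme, at -1.09 fell. The other named rises were VASH2 at 2.28, CCSAP at 1.79, MTHFD2 at 1.20, AMD1 at 1.08 and UCK1 at 1.07, and the other falls RCSD1, STK17A, ASB14, H1-10, TMEM120A, MIGA2 and SLC37A1, at -1.27 to -0.88. Of 30 unfolded protein and heat shock genes 2 rose and 0 fell, HSPH1 and DNAJB4 (5 and 0 adjusted over the list alone), with a median of 0.06 (camera adjusted p = 1.4e-07; adjusted p = 0.543 with an estimated correlation). HSPA4 was not in that list. Interferon genes had a median of -0.58 with 0 of 21 called (6 lower adjusted over the list alone; camera adjusted p = 4.6e-04), IFIH1 standing at -0.79. Ribosomal protein genes had a median of 0.09 with 0 of 62 called, also adjusted over the list alone (camera adjusted p = 4.5e-09). Fatty acid oxidation genes had a median of -0.15 with 0 of 26 called (2 lower adjusted over the list alone; camera adjusted p = 0.708). Slow-type genes had a median of 0.07 and nuclear oxidative phosphorylation genes of 0.00, with 0 called in each, also adjusted over the list alone (camera adjusted p = 0.0101 and 0.00619, the latter 0.0714 with the fibroblast level as a covariate). SHFD_SOL 4 had a slow-type mean of 10.0 against 8.55 to 8.98 in the other 3 of its group. With an estimated correlation the adjusted p was 0.967 for each of these 5 lists. None of the fixed diet genes passed, PDK4 standing at -0.79, CD36 at -0.71, LPL at -0.70, PLIN2 at 0.68, FABP3 at -0.61, UCP3 at -0.58, PPARGC1A at -0.54, FABP4 at -0.36, ANGPTL4 at 0.29, ADIPOQ at -0.12, CPT1A at 0.05 and FASN at -0.05.

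In all, 18 genes rose and 43 fell under SHFD in SOL, so that 29.5% of the calls were rises, against 65.9% after quantile normalization (58 and 30) and 18.8% with nuclear scaling (22 and 95). The median of all genes moved from -0.12 to 0.00 after quantile normalization and was -0.15 with nuclear scaling. With only the 8 libraries compared 3 genes were called, and 19 of the 20 called genes named by rule lost their call (adjusted p from 0.108 to 0.171). The count was 9, 205, 3 and 191 without SHFD_SOL 1, 2, 3 and 4 and 18, 10, 24 and 13 without CONT_SOL 1, 2, 3 and 4. Of the 20 named genes 16 lost their call without SHFD_SOL 1 (adjusted p up to 0.187), 19 without SHFD_SOL 3 (0.148) and 1 without SHFD_SOL 4 (0.0605), and 15, 16, 12 and 15 without CONT_SOL 1, 2, 3 and 4 (0.127, 0.0960, 0.117 and 0.112). Without the expression filter 13 lost it (0.0759), 6 with a pseudocount of 0.1 (0.200) and after quantile normalization 1 (0.0574). AFAP1 kept it in each of the fits without 1 library but not with only the 8 libraries compared.

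After 60 days of high-fat diet, 4 of 15 clock genes rose in SOL and 1 fell (camera adjusted p = 3.0e-06; adjusted p = 0.147 with an estimated correlation). PER3 (3.64 ± 0.536 against 0.802 ± 0.225 FPKM, log2 fold change 1.36, adjusted p = 2.0e-05), PER2 (16.7 ± 3.85 against 4 ± 0.718 FPKM, log2 fold change 1.81, adjusted p = 6.7e-05) and NR1D2 (33.3 ± 5.98 against 10.6 ± 1.7 FPKM, log2 fold change 1.57, adjusted p = 3.7e-04) rose. NPAS2, an activator of the clock, fell at -0.64 (adjusted p = 0.018). TET2 (25.2 ± 5.43 against 2.4 ± 2.51 FPKM, log2 fold change 3.15, adjusted p = 0.00214) rose as it did in PEM. PRKAG2 (32.8 ± 10.1 against 9.62 ± 5.27 FPKM, log2 fold change 1.73, adjusted p = 3.7e-04), a subunit of AMP-activated kinase, rose in SOL too. Further rises were BEST3 (38 ± 5.28 against 14.2 ± 2.64 FPKM, log2 fold change 1.37, adjusted p = 0.00126), a chloride channel, and PPARA (11.9 ± 2.32 against 4.14 ± 1.85 FPKM, log2 fold change 1.39, adjusted p = 0.0202), the receptor that drives fatty acid oxidation genes. ABHD6 (3.03 ± 0.524 against 9.73 ± 1.55 FPKM, log2 fold change -1.41, adjusted p = 5.4e-04), a monoacylglycerol lipase, and PLPP3 (12.8 ± 2.19 against 23.4 ± 1.48 FPKM, log2 fold change -0.84, adjusted p = 0.00216), a lipid phosphatase, fell. ACSL1 (94.7 ± 14.3 against 224 ± 72.1 FPKM, log2 fold change -1.18, adjusted p = 0.0369) fell too. The other named rises were NR4A3 at 2.35, RAD54L2 at 1.64, KDM7A at 0.90 and the sugar transporter SLC2A12 at 0.88, and the other falls GPAT3, VOPP1, SLC5A6, ANKZF1, TOR1AIP2, ABCC8 and NUP205, at -1.12 to -0.60.

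Adjusted over the list alone 6 clock genes rose and 2 fell, and the list had a median of 0.31. The 4 called as higher were PER2, PER3, NR1D2 and NR1D1. Of 26 fatty acid oxidation genes 0 rose and 1, ACSL1, fell (2 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.0316; adjusted p = 0.942 with an estimated correlation, and 0.0512 with the adipocyte marker level as a covariate). Of 21 uptake and droplet genes 0 were called, also adjusted over the list alone, with a median of -0.41 (camera adjusted p = 0.0757, or 0.0391 with the fibroblast marker level as a covariate). Of 19 PPAR and PGC-1 genes 1, PPARA, rose (1 adjusted over the list alone), the median being -0.05 and the mean 0.05 with camera's direction up (adjusted p = 0.374). Of 20 immediate early genes 1, NR4A3, rose (1 adjusted over the list alone; camera adjusted p = 0.107). Fast-type genes had a median of 0.36 with 0 of 17 called, also adjusted over the list alone (camera adjusted p = 0.00820; adjusted p = 0.942 with an estimated correlation, and 0.250 with the adipocyte marker level as a covariate). For this list CONT_SOL 3, at 8.83 against 9.54 to 9.62, and LHFD_SOL 4, at 9.20 against 9.80 to 9.91, stood apart in their groups. None of the fixed diet genes passed, FABP3 standing at -1.12, CD36 at -1.05, PDK4 at -0.58, PLIN2 at 0.56, ANGPTL4 at -0.46, PPARGC1A at 0.27, FABP4 at -0.20, UCP3 at 0.20, CPT1A at -0.18, ADIPOQ at -0.15, LPL at 0.10 and FASN at 0.08.

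In all, 25 genes rose and 32 fell under LHFD in SOL. The count was 110 after quantile normalization and 27 with a pseudocount of 0.1. It was 25, 19, 19 and 29 without LHFD_SOL 1, 2, 3 and 4 and 16, 37, 27 and 37 without CONT_SOL 1, 2, 3 and 4. Of 22 called genes named by rule, the numbers that lost their call were then 13, 11, 13 and 8, with adjusted p up to 0.144, 0.116, 0.125 and 0.133, and 14, 6, 10 and 9, with adjusted p up to 0.171, 0.114, 0.135 and 0.0959. With only the 8 libraries compared PRKAG2, RAD54L2, ACSL1, GPAT3, VOPP1, SLC5A6 and ABCC8 lost theirs (adjusted p from 0.0558 to 0.119). Without the expression filter 6 lost it (up to 0.0677) and 10 with a pseudocount of 0.1 (0.109). TET2, PER2, PER3, NR1D2, BEST3, ABHD6 and PLPP3 kept theirs in all alternatives run. HADHA, a fatty acid oxidation gene at -0.81 with an adjusted p of 0.0704, passed as lower without CONT_SOL 2 (0.00747) and after quantile normalization (0.0445).

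**Figure D3:**
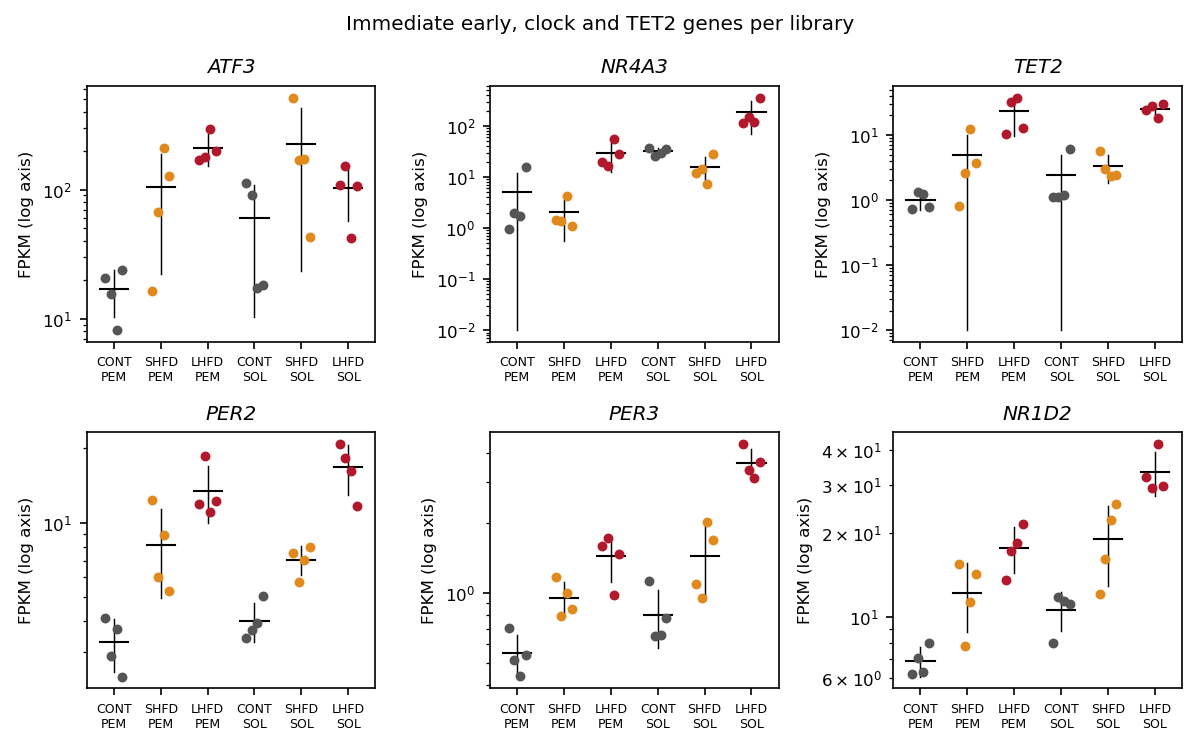
FPKM per library, on log axes with a different range in each panel, of ATF3, NR4A3, TET2, PER2, PER3 and NR1D2 in the 6 groups (points, libraries; horizontal lines, means; vertical lines, ± SD, drawn down to 0.01 where it would fall below). TET2 averaged 23.3 ± 13.8 in LHFD_PEM and 25.2 ± 5.43 in LHFD_SOL against 1.02 ± 0.311 in CONT_PEM and 2.4 ± 2.51 in CONT_SOL, where 1 library stands above the other 3.

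Between the high-fat diets in SOL, 3 of 15 clock genes and 3 of 19 PPAR and PGC-1 genes were higher after 60 than after 15 days. Their lists had camera adjusted p of 7.7e-05 and 0.002, with adjusted p = 0.334 and 0.696 with an estimated correlation. NR4A3 (186 ± 116 against 15.5 ± 9.27 FPKM, log2 fold change 3.48, adjusted p = 0.00256), TET2 (25.2 ± 5.43 against 3.35 ± 1.53 FPKM, log2 fold change 2.62, adjusted p = 0.00937) and NOCT (85.4 ± 56 against 16.2 ± 1.26 FPKM, log2 fold change 2.14, adjusted p = 0.00993), a clock-controlled phosphatase, had the largest rises. UCK1 at -1.18, RPS6KA1 at -1.13 and TSPAN9 at -0.96 had the largest falls. The clock genes were PER3 at 0.95, PER2 at 1.11 and NR1D1 at 0.86 (8 higher and 0 lower adjusted over the list alone), and the list had a median of 0.55. The PPAR and PGC-1 genes were PPARA (11.9 ± 2.32 against 4.32 ± 2.59 FPKM, adjusted p = 0.0136), its partner RXRA at 1.10 and the coactivator PPARGC1A at 0.81. Adjusted over the list alone 5 genes of the list were higher and 1 lower. Of 19 fibre type transcription factors 2 were higher, NFATC1 (44.9 ± 15.7 against 15.9 ± 5.36 FPKM, adjusted p = 0.00688), a calcineurin target that drives slow genes, and FNIP1 at 1.46, which restrains oxidative fibres (5 adjusted over the list alone; camera adjusted p = 0.164). SHFD_SOL 4 stood apart from the other 3 of its group, with a mean of 7.20 against 9.42 to 9.77 for fast-type genes, and had the highest slow-type mean, 10.0 against 8.55 to 8.98. LHFD_SOL 4 had a fast-type mean of 9.20 against 9.80 to 9.91. Slow-type genes had a median of -0.57 (1 lower adjusted over the list alone), fast-type genes of 0.66 (0 adjusted over the list alone) and glycolysis genes of 0.42 (6 higher adjusted over the list alone). With 0 members called in each, their camera adjusted p were 0.002, 0.00188 and 8.7e-04, with adjusted p = 0.705, 0.807 and 0.696 with an estimated correlation. Nuclear oxidative phosphorylation, fatty acid oxidation and ribosomal protein genes had medians of -0.03, -0.08 and -0.08 with 0 called, also adjusted over the list alone. Their camera adjusted p were 0.00640, 0.0357 (0.152 with the fibroblast level as a covariate) and 1.1e-04, with adjusted p = 0.819, 0.807 and 0.819 with an estimated correlation. Heat shock genes had a median of -0.08 (2 lower adjusted over the list alone; camera adjusted p = 0.00188; adjusted p = 0.696 with an estimated correlation) and interferon genes of 0.32 (1 higher adjusted over the list alone; 0.00461; adjusted p = 0.807 with an estimated correlation), with 0 called. Of the fixed diet genes only PPARGC1A passed (adjusted p = 0.0481). In all, 68 genes were higher and 29 lower, 70.1% of the calls being higher, against 54.2% after quantile normalization. The count was 41 with only the 8 libraries compared, 38, 68, 39 and 98 without LHFD_SOL 1, 2, 3 and 4, and 35, 199, 61 and 85 without SHFD_SOL 1, 2, 3 and 4. Of the 14 called genes named by rule 6, 4, 6 and 4 lost their call without LHFD_SOL 1, 2, 3 and 4 (adjusted p up to 0.165, 0.107, 0.150 and 0.0965). The numbers were 6, 2, 5 and 3 without SHFD_SOL 1, 2, 3 and 4 (up to 0.189, 0.0590, 0.151 and 0.127). With only the 8 libraries compared UCK1, PPARGC1A, NR1D1, RXRA, PPARA, NFATC1 and FNIP1 lost theirs (adjusted p from 0.0658 to 0.131) and TBX15 passed (0.0498), as NFATC2 did after quantile normalization (0.0367) and NR1D2 without SHFD_SOL 4 (0.0316). Without the expression filter 5 lost it (up to 0.0985) and 2 with a pseudocount of 0.1 (0.168). NR4A3, TET2, NOCT and PER3 kept theirs in all alternatives run.

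The diet responses were compared within and between muscles. In PEM, 42 genes rose and 49 fell under both SHFD and LHFD, and 0 went opposite ways. Independent lists of these sizes would share 1.21 and 2.84, and in 20 draws of simulated unchanged groups against the same controls 0 genes were called, so the 0 they shared gives no value for the overlap. When the 4 control libraries were split 2 and 2 between the diets, in 6 ways, 0 to 8 rises and 1 to 13 falls were shared and up to 2 genes went opposite ways, where independent lists would share up to 0.37 and 0.70. In SOL 1 gene rose and 6 fell under both, where independent lists would share 0.04 and 0.13, and with split controls 1 rise and 0 falls were shared, against up to 0.01. Between muscles, whose libraries are not shared, 14 genes rose under LHFD in both, against 0.51 for independent lists, and 11 fell, against 1.57. Those that rose included PER2, PER3, NR1D2, TET2, NR4A3, BEST3, RAD54L2, SLTM, PISD and FOXO6, and those that fell ACSL1, PLPP3, TOR1AIP2, ANKZF1, ADCK1, ALKBH8, XRCC5, CENPT, PIGQ and DUS3L. Under SHFD 1 gene rose in both muscles, SYNPO2L, against 0.10, and 4 fell, RFX5, APLF, PNRC1 and H1-10, against 0.23. Which birds the muscles share is not given in the sources used here, so values for independent lists need not be those without an effect. The genes of this paragraph not described above were chosen after their values were seen.

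Whether the diet effect differed between muscles was tested as the difference of the effects, SOL minus PEM. For SHFD, 1 gene passed, ENSGALG00000051520 (no symbol given), chosen by its smallest p after the values were seen. It averaged 46.4 ± 11.8 FPKM in SHFD_SOL against 2.03 ± 0.238 in CONT_SOL, and 1.14 ± 0.516 in SHFD_PEM against 1.13 ± 0.794 in CONT_PEM (difference of log2 fold changes 3.89, SE 0.46, adjusted p = 2.5e-04). For LHFD, limma called 0 genes, with 620 at an unadjusted p under 0.05, and the same gene, at 24 ± 14.1 FPKM in LHFD_SOL and 1.70 ± 1.44 in LHFD_PEM, had a difference of 2.62 with an adjusted p of 0.105. That gene passed after quantile normalization (adjusted p = 0.0241), without LHFD_PEM 4 (0.0046) and without CONT_PEM 2 (0.0356). MYOT had differences of -1.56 for SHFD and -1.71 for LHFD with adjusted p of 0.187 and 0.106, and CPT1A of 0.18 and 1.29 with 0.969 and 0.338. After quantile normalization MYOT passed for both, at adjusted p of 0.0437 and 0.0333. It passed for LHFD also without LHFD_SOL 4 (0.0397) or CONT_PEM 2 (0.0328). The LHFD count was 1 without LHFD_SOL 4, CONT_SOL 2 or LHFD_PEM 2, 2 without LHFD_PEM 4, 3 without CONT_SOL 4 or CONT_PEM 4 and 9 without CONT_PEM 2. The SHFD count was 2 without SHFD_PEM 4, CONT_PEM 2 or CONT_PEM 4. For LHFD the immediate early list stood lower in SOL minus PEM, with a median of -0.85 and 0 of 20 called (1 lower adjusted over the list alone; camera adjusted p = 6.1e-09; adjusted p = 0.373 with an estimated correlation). For SHFD the ribosomal protein list had a median difference of 0.27 with 0 of 62 called, also adjusted over the list alone (camera adjusted p = 4.2e-21; adjusted p = 0.968 with an estimated correlation). The TCA cycle list had -0.27 for SHFD (camera adjusted p = 5.5e-05; adjusted p = 0.968 with an estimated correlation). For LHFD slow-type, extracellular matrix and fibroblast genes had -0.70, -0.42 and -0.35, and clock genes 0.30 (camera adjusted p = 0.00356, 1.0e-05, 0.00394 and 0.0263), each with an adjusted p of 0.762 with an estimated correlation. With the fibroblast level as a covariate the matrix list had 0.139 and the clock list 0.0777, or 0.0532 with the adipocyte level. The fibroblast level called the ribosomal (2.2e-09), macrophage (0.00217) and lymphocyte (0.00298) lists up for LHFD and the last 2 up for SHFD (1.0e-05 and 3.7e-04), none called without it. In these 5 lists 0 were called, and adjusted over the list alone 1 clock gene was higher. Genes called in one muscle only are thus not shown to respond differently, apart from ENSGALG00000051520 for SHFD, with chance left open (splits below).

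**Figure D4:**
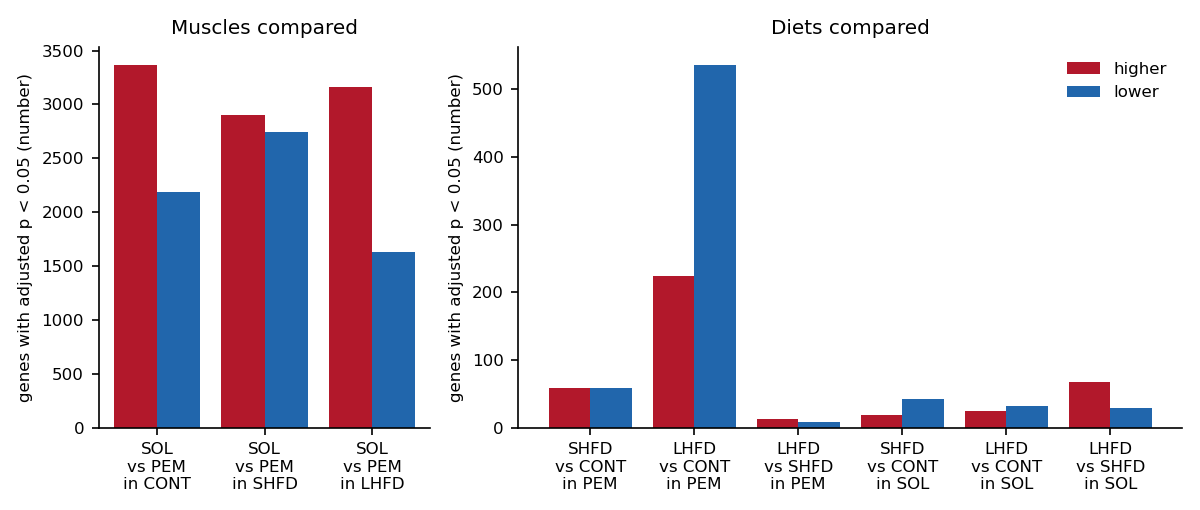
Number of genes with an adjusted p under 0.05, higher (red) and lower (blue) in the group named first, for the 3 comparisons of muscles and, on an axis of its own, the 6 comparisons of diets. LHFD against CONT in PEM called 224 genes higher and 536 lower, the most of the diet comparisons, but after quantile normalization 318 and 343.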

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

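All tests of explanations in this part, the splits included, were chosen only after the results were seen.

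PER2, PER3 and NR1D2 were higher under LHFD in both muscles. With each marker list mean added as a covariate, the highest adjusted p of PER2 and NR1D2 in either muscle was 0.0139. After quantile normalization the highest of the 3 genes was 0.01. This argues against RNA from other cells for that pair of genes and against the scaling for all 3. For PER3 the highest was 1.1e-04 in SOL, which argues against other cells there. In PEM it was 0.103, where the smooth muscle and pericyte level was added and the fold change went from 0.65 (SE 0.14) to 0.57 (SE 0.19), the call ending with the wider error, so other cells stay open for PER3 in PEM. A difference in the hour of collection between diets could also give the pattern: the clock activators ARNTL, CLOCK and NPAS2 had a mean log2 fold change of -0.25 in PEM and -0.44 in SOL, but the hour, which the sources used here do not give, and the diet cannot be told apart. A response of the clock to the diet stays open as a hypothesis.

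The immediate early genes were higher under LHFD in PEM, by 1.07 (SE 0.25) in the list mean. Without CONT_PEM 2 and LHFD_PEM 1, which stand apart, the difference was 1.20, and with each marker list mean as a covariate it was at least 0.996, which argues against those libraries and against other cells as the whole source. Handling of the whole bird before death could raise such genes and would act on both muscles; the list's difference of effects between muscles had an adjusted p of 0.373 with an estimated correlation, which does not decide it. The list mean was 3.47 ± 0.263 in CONT_PEM, 3.36 ± 0.210 in SHFD_PEM and 4.55 ± 0.274 in LHFD_PEM, and 4.50 ± 0.548, 4.27 ± 0.401 and 4.68 ± 0.336 in the same diets of SOL. A response to the diet and handling cannot be told apart, since handling would follow the diet groups.

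CONT_PEM 2 held 10484 genes at 1 FPKM or more, against 9285 to 9432 in the other CONT_PEM libraries, and 380 genes reached 1 FPKM in it and in no other PEM library. Genes that SOL libraries hold and other PEM libraries lack reached at most 0.168% of their SOL level in it, and its globin genes at most 0.378 of the highest of the other CONT_PEM libraries, which argues against soleus RNA and blood. Macrophages and lymphocytes in the tissue block are a candidate explanation: its macrophage and lymphocyte list means exceeded those of every other library by at least 0.717 on the log2 scale. SPP1 stood at 217 FPKM against 0 to 0.121 in the other 3 libraries, JCHAIN at 265 against 2.17 to 11.1 and CTSK at 174 against 4.48 to 5.73; 8 macrophage and 4 lymphocyte members were at 1 FPKM or more in all libraries. No biological explanation was tested.

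Other splits of the same libraries were set against the real ones, 35 for each pair of groups. For the muscles only 1 split, the real one, gave as many genes in CONT (5554, highest other 892), SHFD (5646, 279) and LHFD (4795, 3). The same held for SHFD and LHFD against CONT and LHFD against SHFD in PEM (117, 760 and 22, highest others 11, 275 and 4). It also held for SHFD and LHFD against CONT in SOL (61 and 57, highest others 10 and 3). A share of 1 in 35 is under 0.05 for a pair taken alone, but it is the lowest that 35 splits allow. With several pairs examined after the results were seen, it does not exclude chance. For LHFD against SHFD in SOL 2 of 35 splits gave as many as 97, the other one 156, so the share was not under 0.05. Nor was it for the SHFD difference of effects, where 16 of 100 splits gave 1 gene or more (highest 12). For the LHFD difference the real count was 0, which all 100 splits reach by design (highest 209), so they decide nothing. Splits that call several times the real count point to a structure of the samples. In CONT, 8 splits part every same-numbered pair, too few for a share under 0.05, and the real one gave 5554 and the highest other 718.

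The SHFD effect on ENSGALG00000051520 differed between muscles by 3.89 (log2) in limma, with chance left open. Single libraries far from the other 3 of their group were found in 47 of 637 groups tested, and chance flags about 1 in 20 groups. CONT_SOL 3 had the lowest mean correlation with its group, 0.976 against 0.978 for the others. Fast-type list means were 8.83 in CONT_SOL 3 (others 9.54 to 9.62), 7.20 in SHFD_SOL 4 (9.42 to 9.77) and 9.20 in LHFD_SOL 4 (9.80 to 9.91). The fibre type transcription factor mean was 3.82 in SHFD_PEM 4 (3.62 to 3.64) and 4.20 in CONT_SOL 3 (4.02 to 4.04), the TCA cycle mean 7.15 in SHFD_SOL 2 (6.93 to 6.95), the nuclear oxidative phosphorylation mean 6.15 in CONT_PEM 3 (6.25 to 6.26) and the fatty acid uptake mean 3.98 in SHFD_PEM 1 (3.70 to 3.72). The lymphocyte mean was 2.55 in LHFD_PEM 1 (1.29 to 1.33), the satellite cell mean 3.17 in CONT_PEM 2 (2.85 to 2.88) and the skin epithelium mean 2.20 in CONT_PEM 1 (1.28 to 1.39).

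For named genes, FPKM of the library that stood apart and, in brackets, the range of the group's other 3 follow. CONT_PEM 1 held ETFA at 40.4 (31.1 to 31.7), MYL3 at 3.41 (0.0482 to 0.332) and TNNI1 at 6.11 (0.0715 to 0.347). CONT_PEM 2 held COX6A1 at 42.6 (17.5 to 19.7), FABP4 at 44.3 (4.11 to 5.06), FABP5 at 21.4 (13.3 to 14.4) and FASN at 2.32 (0.755 to 0.826). CONT_PEM 3 held GADD45G at 63.6 (8.18 to 11.6), LDHA at 7474 (9813 to 9903) and PGAM1 at 5387 (6610.0 to 6841). CONT_PEM 4 held KDR at 1.04 (2.38 to 2.71) and RRAD at 19 (0.353 to 1.07). CONT_SOL 1 held ANGPTL4 at 2.31 (0.537 to 0.647), NR1D2 at 8.06 (11.1 to 11.8) and RYR3 at 41.9 (30.3 to 31.4). CONT_SOL 3 held SOX6 at 1.00 (2.13 to 2.28), TPM1 at 744 (1437 to 1495) and UCK1 at 11.6 (7.63 to 8.01). CONT_SOL 4 held KDM7A at 9.28 (6.46 to 6.83), PRKAG2 at 17.5 (6.57 to 7.28), TET2 at 6.17 (1.1 to 1.22) and XIRP1 at 40.5 (76.3 to 84.8). LHFD_PEM 1 held HADH at 113 (69.3 to 74.2), MYH1E at 10850.0 (13310.0 to 13580.0) and PDK4 at 17.1 (88.9 to 120.2). LHFD_PEM 2 held GLUL at 73.6 (30.3 to 34.4). LHFD_PEM 4 held DGAT2 at 26.1 (6.73 to 8). LHFD_SOL 2 held PDK4 at 256 (713 to 878). LHFD_SOL 4 held RXRA at 20.5 (28.2 to 29.8). SHFD_PEM 2 held MYOT at 103 (141 to 149). SHFD_PEM 4 held FXYD6 at 18 (8.04 to 9.04). SHFD_SOL 4 held PPARA at 8.18 (2.83 to 3.37), PVALB at 0.0161 (10.5 to 17.9) and TNNI2 at 1320.0 (5494 to 6360.0).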

How the results depend on the processing

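Only the alternatives listed above as added later were not planned. Without counts, DESeq2 and a change of measure were not run, and quantile normalization replaced another count scaling. The 3 muscle counts stayed within 1.5 times in all alternatives, from 5015 to 5976 in CONT, 5147 to 5435 in SHFD and 4123 to 4847 in LHFD with 1 library left out. With only the groups compared in the fit, which leaves fewer libraries for the spread, the counts were 0 (SHFD, PEM; 1444 genes at an unadjusted p under 0.05 in the fit of all libraries), 69 (LHFD, PEM), 10 (LHFD against SHFD, PEM), 3 (SHFD, SOL) and 41 (LHFD against SHFD, SOL). With quantile normalization they were 11 (LHFD against SHFD, PEM), 110 (LHFD, SOL) and 2 for each difference of effects. Nuclear scaling gave 12 (LHFD against SHFD, PEM) and 117 (SHFD, SOL), a pseudocount of 0.1 gave 40 (SHFD, SOL) and 27 (LHFD, SOL), and no filter gave 35 (SHFD, SOL). Without CONT_PEM 2 and LHFD_PEM 1 they were 180 (SHFD, PEM), 12 (LHFD against SHFD, PEM), 2 (SHFD difference) and 8 (LHFD difference). Leaving out 1 library gave 47 to 173 (SHFD, PEM), 393 to 953 (LHFD, PEM), 9 to 30 (LHFD against SHFD, PEM), 3 to 205 (SHFD, SOL), 16 to 37 (LHFD, SOL), 35 to 199 (LHFD against SHFD, SOL), 1 to 2 (SHFD difference) and 0 to 9 (LHFD difference). The cause of these changes, those in the smaller fits included, was not tested.

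The replicate block, which across diets joins different birds by number, gave 9 (LHFD against SHFD, PEM), 23 (SHFD, SOL) and 1 (LHFD difference). These do not test pairing, and no other count moved by over 1.5 times. Same-numbered muscles correlated at 0.075 to 0.362 in SHFD, each best with its own number, and at -0.119 to 0.094 in LHFD. There SOL 2, 3 and 4 went best with PEM 1, 2 and 3 (0.242 to 0.331). These are hints of shared birds, not the design. Of 233 called results of named genes, 133 kept their call in all alternatives, 69 lost it in at least 1 fit without a library, 96 in at least 1 other alternative, and 0 changed direction. Over all comparisons and lists, marker level covariates ended 28 camera calls and added 55. Unknown depth limits claims on genes with low values.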

Other observations

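The genes and tests of this part were chosen after the values were seen. Under the control diet HOXC10, a homeobox gene of the posterior body axis, averaged 35.6 ± 2.05 FPKM in SOL and 0.0636 ± 0.0462 in PEM (log2 fold change 5.11, adjusted p = 4.1e-18). HOXC11 averaged 3.50 ± 0.985 in SOL and was listed at 0 in the 4 CONT_PEM libraries. PITX1, a gene of hindlimb identity, averaged 2.60 ± 1.55 and 0.0159 ± 0.0199. HOXA7 (13.7 ± 1.21 against 39.3 ± 1.76, log2 fold change -1.46, adjusted p = 1.6e-07) and MEIS1 (1.96 ± 0.455 against 12.8 ± 2.89, -2.21, adjusted p = 3.9e-10) were lower in SOL. Of 16 tested HOX genes 8 were higher and 5 lower in SOL, a majority that turned to 5 and 6 after quantile normalization, and 9 were called in all 3 diets. Of all genes tested 50.7% were called in this comparison, and whether the family is called more often was not tested. Both ZIC genes were higher, and of 6 TBX genes 3 were higher and 0 lower, or 2 and 1 after quantile normalization.

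Whether a high-fat diet moves PEM towards SOL was checked with muscle comparisons from the other high-fat diet. Of 59 genes that rose under SHFD, 9 were higher in SOL under LHFD, 15.3% against 28.9% of all genes, and of 224 that rose under LHFD 64 were higher in SOL under SHFD, 28.6% against 26.5%. Of the genes that fell, 7 of 58 (12.1% against 14.9%) and 180 of 536 (33.6% against 25.1%) were lower in SOL. The rises did not show the excess that the hypothesis needs.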
